A study of Mus musculus with 13 samples.

How the data were processed

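Gene expression was measured by bulk RNA-seq in mouse embryonic fibroblasts (MEFs) that lack Tet2 and carry doxycycline-inducible reprogramming factors (Pou5f1, Klf4, Sox2 and Myc, called OKSM). Per the labels' protocols, the day 5 cells were infected with a pMXs retrovirus that was empty or carried wild-type Tet2 (Tet2-WT) or a stalling mutant (Tet2-E). They were then grown on growth-arrested feeder MEFs in medium with LIF, 1 µM PD0325901 (an inhibitor of ERK signalling), 3 µM CHIR99021 (an activator of beta-catenin) and 2 µg/mL doxycycline. The protocols name no sort and no removal of feeder cells, so a day 5 library is read here as the whole culture. Untreated MEFs are, per the series labels, of the same Tet2-null line and not reprogrammed, and the labels leave unclear whether they carry the empty vector. Libraries came from stranded mRNA selection and were sequenced in pairs of short reads. The labels state that they were prepared in 2 sets but not which library was in which.

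The values are raw read counts per gene, which the authors made by alignment with STAR 2.6.1a to mm9 and counting with featureCounts 1.6.2, per the submitters' processing notes. The notes also name SAMtools 1.7, bedtools 2.27.1, R 3.6.2 and DESeq2 1.26.0. The strand setting of the counting is not stated, and no coordinates were used here. The deposited counts table held 24495 genes in 13 libraries: 3 untreated, 3 pMXs, 3 Tet2-WT and 4 Tet2-E. Total counts per library ran from 14052646 to 26265382.

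Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (count minimum 10, total minimum 15), which left 14607. Libraries were scaled by TMM, and 1 robust quasi-likelihood fit with a mean per group served all 4 comparisons. Adjusted p-values are Benjamini-Hochberg values from edgeR over all genes tested within a comparison, and a gene is said to have risen, fallen or changed when its value was under 0.05. Log2 fold changes are given with an approximate standard error, the absolute change divided by the square root of the quasi-likelihood F value. Levels are in counts-per-million (CPM) with the standard deviation between libraries. The biological coefficient of variation was 0.102. Differences between replicates exceeded counting error, with a chi-square per degree of freedom of 6.3 to 40.4 over pairs of replicates, so depth was not the main limit on precision for abundant genes. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries.

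The comparisons, the tests, the gene lists and the rule for naming genes were chosen before the data were examined. Named genes were Tet2, Tet1, Tet3, Tdg and the OKSM genes. To these came, in each comparison, the 8 higher and 8 lower genes with the smallest p among those changed by at least 1 on the log2 scale, with at least 5 CPM in 1 of the groups and no overlap between their libraries, unnamed gene models left out. From each list came up to 2 members that rose and 2 that fell with the largest change and at least 1 CPM, or the 2 with the smallest p where none passed. A gene named in 1 comparison stayed named in the others.

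The 21 lists were OKSM factors, cytosine methylation and demethylation machinery, epithelial genes, mesenchymal and fibroblast genes, the pluripotency network, germline genes, imprinted genes, cell cycle genes, p53 targets and senescence barrier, interferon response genes, ERK pathway targets, beta-catenin targets, TGF-beta targets, glycolysis genes, and markers of macrophages, endothelium, skeletal muscle, neural cells, keratinocytes, extraembryonic tissue and germ layers, and erythroid cells. Each list was tested against all other genes by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 21 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it.

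Alternatives were DESeq2 size factors in edgeR (RLE), DESeq2 1.42.0, no filter, at least 1 CPM in 3 libraries, a term for the replicate number (replicate block), 1 surrogate variable from sva 3.50.0, a fit of only the 2 groups compared, and leaving out each library in turn. The replicate numbers 1, 2, 100 and 250 recur across groups, so pairing was checked on residuals after group means. Pairs of day 5 libraries with the same number correlated at 0.12 to 0.34 across genes and pairs with another number of the same set (1 with 2, 100 with 250) at 0.08 to 0.36, against -0.42 to -0.05 for pairs from opposite sets. The numbers were therefore taken to link the day 5 libraries, mostly through these sets, and not the untreated ones, where same-number pairs gave -0.04 to 0.17. A term for the set and contrasts within each set were added after seeing the data. Tet2-WT has 2 libraries of the first set and 1 of the second, pMXs has 1 and 2, and Tet2-E has 2 of each.

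The procedure was tested on simulated data at the real depths and group sizes, with 200 genes changed 1.5-fold or 2-fold. It recovered 62.2 to 73.7% of genes changed 1.5-fold and 84.8 to 88.8% of genes changed 2-fold, with 3.03 to 5.62% false calls, over the 4 comparisons. A planted list of 30 genes, 15 of them raised 1.5-fold, was called in each comparison, and 0 of the 21 real lists were. The simulated genes were drawn independently of each other and without the sets of replicate numbers. The 0 is therefore no check on false list calls among correlated genes or from these sets.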

Results

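RNA-seq counts were available for 13 libraries in 4 groups: untreated Tet2-null MEFs (n = 3), and cells at day 5 of reprogramming with the empty pMXs vector (n = 3), with Tet2-WT (n = 3) or with Tet2-E (n = 4). Total counts were 21985590 to 25991708 in untreated libraries, 14310277 to 25326826 with pMXs, 20261396 to 25720579 with Tet2-WT and 14052646 to 26265382 with Tet2-E. The first principal component of log2 CPM carried 82.8% of the variance and the second 5.4%.

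Tet2 itself was read first, since the cells lack the working gene and the vectors supply it. Tet2 RNA was 37.8, 45.4 and 48.3 CPM in untreated replicates 1, 2 and 100, and 58.8, 39.1 and 41.1 CPM in pMXs replicates 2, 100 and 250. With Tet2-WT it was 1240, 1180 and 1230 CPM in replicates 1, 2 and 250. With Tet2-E it was 1360, 1400, 581 and 1300 CPM in replicates 1, 2, 100 and 250. Tet2 rose over pMXs with Tet2-WT (log2 fold change 4.72 ± 0.31, adjusted p = 3e-06) and with Tet2-E (4.65 ± 0.30, adjusted p = 3.89e-05). A difference between Tet2-WT and Tet2-E did not pass (0.07 ± 0.24, adjusted p = 0.964), nor did one between pMXs and untreated cells (0.08 ± 0.28, adjusted p = 0.815). The counts do not part vector RNA from RNA of the disrupted locus or of feeder cells, so the level without a Tet2 vector says nothing about working Tet2. Of the related genes, a change of Tet1, Tet3 and Tdg with Tet2-WT did not pass (edgeR adjusted p = 0.393, 0.214 and 0.21). Their means were lower than with pMXs, Tet1 at 17 ± 6.37 against 24.4 ± 9.66 CPM and Tet3 at 91.2 ± 18.3 against 111 ± 13.4 CPM. Tdg, at 0.433 ± 0.013 against 0.729 ± 0.179 CPM, was near the floor. A change of these genes is thus not excluded.

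**Figure D1:**
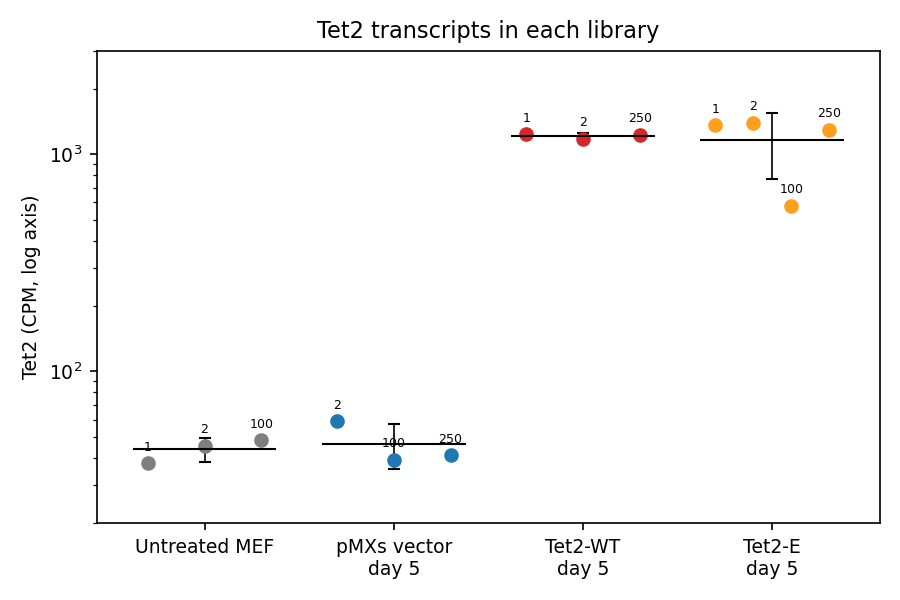
Tet2 RNA in CPM (log axis) in each library of the 4 groups, with dots labelled by replicate number, lines for group means and bars for the SD. All 7 libraries with a Tet2 vector lie at 581 CPM or above, and the 6 without one at 58.8 CPM or below.

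The empty-vector culture against untreated MEFs gives the change that 5 days of OKSM expression, feeder cells and medium bring together without working Tet2, and also that of vector infection if the untreated MEFs carry no vector, which the labels leave unclear. The OKSM genes rose: Pou5f1 by 6.49 ± 0.20 on the log2 scale (211 ± 11.2 against 2.32 ± 0.965 CPM, n = 3 and 3, edgeR adjusted p = 2.48e-12), Sox2 by 6.02 ± 0.21 (adjusted p = 5.85e-12), Myc by 3.10 ± 0.18 (adjusted p = 1.34e-09) and Klf4 by 1.29 ± 0.09 (adjusted p = 9.46e-09). Cdh1, the epithelial cadherin, rose by 8.41 ± 0.25 (305 ± 44.3 against 0.899 ± 0.456 CPM). L1td1, an RNA-binding protein gene of pluripotent cells, rose by 9.65 ± 0.29. Dlk1, an imprinted gene of fetal fibroblasts, went from 540 to 3.33 CPM (log2 fold change -7.38 ± 0.15, adjusted p = 3.46e-14). In all, 10234 of 14607 genes changed, 5118 higher and 5116 lower, and 4200 of them by at least 2-fold. The count lay between 9340 and 10466 in the alternative settings, contrasts within the sets of replicate numbers included. Groups did not overlap for 72% of genes tested, where chance gives 10%.

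The 16 genes with the smallest p among large changes included the adhesion genes Cxadr (4.15 ± 0.08, adjusted p = 3.46e-14) and Cadm1 (4.54), the growth factor binding gene Fgfbp1 (8.03), the cohesin gene Rec8 (6.01), the myelin-family gene Pllp (7.98), the endothelial receptor Tek (4.47), and Bex1 (6.39) and Bex4 (6.40). On the lower side were the choline transporter Slc5a7 (-4.54), Arhgap36 (-6.05), Cdh3 (-3.21), Oaf (-3.45), Wbscr17 (-2.90), the metalloprotease inhibitor Timp2 (-2.28) and Maged2 (-2.10), next to Dlk1.

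Among the lists, 13 of 21 were called by camera. Of the mesenchymal and fibroblast genes 0 rose, 29 fell and 3 did not pass (adjusted p = 4.51e-10, and adjusted p = 0.000768 with an estimated correlation), with Lum at -3.77 and Twist2 at -3.54 ± 0.12. Epithelial genes rose in 26 of 28 and fell in 0 (3.78e-08, and adjusted p = 0.155 with an estimated correlation). Cell cycle genes rose in 29 of 30, among them Rrm2 (1.68) and Aurka (1.88), and E2f1 alone fell (-0.39), for a list value of 7.67e-10, and adjusted p = 0.221 with an estimated correlation. The pluripotency network had 27 rising and 3 falling of 31 (9.83e-06, and adjusted p = 0.155 with an estimated correlation), Klf2 (-1.23) and Lefty1 (-2.01) among those that fell. Zfp42, Dppa2, Dppa3, Dppa4, Dppa5a, Tcl1, Prdm14 and Rex2 were below the filter and were not tested. All 4 OKSM factors rose (0.000871, and adjusted p = 0.155 with an estimated correlation), as set by the design, since doxycycline induces them in these cells. In no comparison do the counts part RNA of the inducible factors from that of the cells' own genes. Glycolysis genes rose in 15 and fell in 3 of 21 (0.000318, and adjusted p = 0.256 with an estimated correlation), 16 and 3 adjusted over the list alone, with the glucose transporter Slc2a3 at 3.96 and Eno3 at -0.56. For every other list the counts adjusted over the list alone equalled those over all genes tested.

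Interferon response genes fell in 22 and rose in 3 of 28 (0.000585, and adjusted p = 0.155 with an estimated correlation): Ifit3 (-4.55) and Ifit1 (-3.68) fell, while Zbp1 (3.09) and Bst2 (0.87) rose. TGF-beta targets fell in 16 and rose in 2 of 23 (0.000585, and adjusted p = 0.155 with an estimated correlation), Cnn1 (-3.10) and Ltbp2 (-2.60) down and Bhlhe40 (2.39) and Skil (0.63) up. The cytosine methylation and demethylation machinery rose in 14 and fell in 1 of 22 (0.00349, and adjusted p = 0.155 with an estimated correlation): Parp1 (1.81 ± 0.07) and Gadd45g (1.91) rose, Polb fell (-0.62), and Tet3 rose by 0.60 ± 0.14 (adjusted p = 0.00129). Tet1 (0.04, adjusted p = 0.92) and Tdg (0.07, adjusted p = 0.9) did not pass. Imprinted genes rose in 7 and fell in 20 of 34 (0.0193, and adjusted p = 0.155 with an estimated correlation), with Ddc at 4.30 and Zim1 at -4.06. Of p53 targets and senescence barrier genes 16 rose and 3 fell of 24 (0.0193, and adjusted p = 0.155 with an estimated correlation), Perp (2.44) and Pmaip1 (1.27) against Cdkn2b (-1.14) and Cdkn2a (-0.38). Skeletal muscle markers fell in 7 of 8 (0.0193, and adjusted p = 0.155 with an estimated correlation), including Myh8 (-3.81) and Tnnt3 (-2.79). Beta-catenin targets rose in 10 and fell in 3 of 16 (0.0451, and adjusted p = 0.155 with an estimated correlation), Sp5 (3.88) and Ascl2 (2.81) up and Nkd1 (-2.59) down, a call lost with the replicate block (0.0768) and without untreated replicate 1 (0.0605), untreated replicate 100 (0.0801) or pMXs replicate 100 (0.051).

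The remaining lists were not called. ERK pathway targets rose in 7 and fell in 10 of 23 (0.835), Egr1 (-5.82) and Egr2 (-4.38) down and Spry4 (1.20) up. Germline genes rose in 1 (Tdrd1, 1.07) and fell in 7 of 11 (0.121), with Ddx4 at -2.88 and Brdt at -1.47. Macrophage markers rose in 3 and fell in 3 of 7 (0.911): Laptm5, a lysosomal membrane gene of blood cells, rose by 8.21 ± 0.26 and Cd68 by 1.78, while Lyz2 fell (-4.01). Cd53 went from 1.21 to 0 CPM. Endothelial markers rose in 5 and fell in 3 of 11 (0.499), with Esam at -2.23 and Flt1 at -1.93. Neural markers rose in 7 and fell in 3 of 17 (0.226), the neuronal regulators Neurog2 (8.15) and Neurod1 (6.06) up and Gap43 (-4.00) and Map2 (-1.65) down. Keratinocyte markers rose in 8 and fell in 3 of 16 (0.132), with Krtdap (4.65) up, and with the replicate block the list was called (0.0386). Extraembryonic and germ-layer markers rose in 6 and fell in 5 of 13 (0.878), with Tfap2c (8.37) and Plet1 (5.27) up and Krt7 (-2.19) and Gata6 (-1.82) down. Of the 2 erythroid markers tested 1 rose and 0 fell (0.281), and Alas2 did not pass (0.49, adjusted p = 0.361).

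Tet2-WT against pMXs asks what working Tet2 changes by day 5. P2rx7, an ATP-gated channel gene, rose by 2.10 ± 0.11 (79.5 ± 6.66 against 18.5 ± 2.5 CPM, n = 3 and 3, edgeR adjusted p = 6.43e-08). Chst3, a chondroitin sulfotransferase gene, rose by 1.66 ± 0.09 (146 ± 7 against 46 ± 5.64 CPM, edgeR adjusted p = 6.43e-08). The collagen genes Col5a1 and Col1a1 fell, Col5a1 from 840 to 400 CPM (-1.07 ± 0.08, adjusted p = 9.56e-07) and Col1a1 from 8109 to 4705 CPM (-0.79 ± 0.10, adjusted p = 9.95e-05). The chemokine gene Cxcl12 fell from 92.1 to 17.4 CPM (-2.41 ± 0.16, adjusted p = 6.14e-07). The OKSM genes did not pass: Pou5f1 was at 0.31 (adjusted p = 0.191), Klf4 at 0.18 (0.244), Sox2 at 0.20 (0.462) and Myc at 0.20 (0.513). Their means were all higher with Tet2-WT than with pMXs: Pou5f1 262 against 211 CPM, Klf4 491 against 433, Sox2 263 against 228 and Myc 528 against 460. A modest rise of these genes is thus not excluded.

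In all, 1830 genes changed with Tet2-WT, 878 higher and 952 lower, and 529 of them by at least 2-fold, 246 higher and 283 lower. Groups did not overlap for 34.6% of genes tested, where chance gives 10%. The count fell to 1175 without pMXs replicate 100, 1097 without pMXs replicate 250, 1107 without Tet2-WT replicate 1 and 1135 without Tet2-WT replicate 2. Within replicate numbers 1 and 2, 1260 genes were called, and within 100 and 250, 1358, where the arm of each set with 1 library was assumed to vary like the other groups.

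Other genes with the smallest p were the growth factor gene Mst1 (2.29 ± 0.12), the actin regulator Avil (2.03 ± 0.12), the aldehyde and alcohol dehydrogenase genes Aldh3a1 (1.88 ± 0.13) and Adh7 (1.36), the steroid reductase gene Srd5a1 (1.18) and Zfp961 (1.30) on the higher side. On the lower side were Cpxm1 (-1.45), the matrix genes Col11a1 (-1.65), Tnc (-1.17) and Mfap4 (-1.65), the cadherin Cdh3 (-1.27) and Clca3a1 (-1.99).

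Camera called 5 of the 21 lists for Tet2-WT. Mesenchymal and fibroblast genes rose in 2 and fell in 14 of 32, or 3 and 20 adjusted over the list alone (adjusted p = 8.33e-10, and adjusted p = 0.000832 with an estimated correlation). Lum had the largest fall (-2.51, adjusted p = 0.0242, but 0.0656 with no filter on low counts, 0.0711 without pMXs replicate 100, 0.0649 without pMXs replicate 250, 0.095 without Tet2-WT replicate 1 and 0.0942 without Tet2-WT replicate 2). Postn fell by 1.24 ± 0.26 (adjusted p = 0.00802). TGF-beta targets rose in 1 and fell in 7 of 23, or 2 and 7 adjusted over the list alone (0.000127, and adjusted p = 0.213 with an estimated correlation). This list shares Col1a1, Acta2, Tagln and Tgfbi with the mesenchymal list. Col1a1, Tagln and Tgfbi were among the 14 mesenchymal members that fell, so the calls of these lists are not separate findings. Tgfbi, a matrix gene induced by TGF-beta, fell by 1.17 ± 0.10 on the log2 scale (51.1 ± 3.73 against 115 ± 4.53 CPM). Interferon response genes rose in 8 and fell in 0 of 28, or 12 and 1 adjusted over the list alone (0.000127, and adjusted p = 0.213 with an estimated correlation), including Isg15 (1.78 ± 0.29) and Oas1a (2.10 ± 0.47). Both were at low levels, Isg15 at 2.3 against 0.703 CPM and Oas1a at 1.08 against 0.244 CPM. In untreated MEFs Isg15 was 5.6 CPM and Oas1a 0.0944 CPM.

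Macrophage markers rose in 4 and fell in 0 of 7, with the same counts adjusted over the list alone (0.000127, and adjusted p = 0.213 with an estimated correlation): Laptm5 (1.65 ± 0.14, 251 ± 52.1 against 80 ± 7.1 CPM), the integrin gene Itgam (3.18 ± 0.26, 7.13 against 0.791 CPM), Cd68 (1.72 ± 0.19) and Csf1r (2.25 ± 0.44, 0.856 against 0.165 CPM). Csf1r lies outside the naming rule, which asks for at least 1 CPM, and was 1.09 CPM in untreated MEFs. Keratinocyte markers rose in 7 and fell in 0 of 16, or 9 and 1 adjusted over the list alone (0.00018, and adjusted p = 0.229 with an estimated correlation), with Col17a1 at 3.14 ± 0.27 and Krt6a at 2.73.

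The other lists were not called for Tet2-WT. Epithelial genes rose in 3 and fell in 0 of 28, or 2 and 0 adjusted over the list alone (0.074), with the keratins Krt18 (1.77) and Krt8 (1.08). With the replicate block 4 rose and 1 fell, and Cdh1, which had not passed (-0.38, adjusted p = 0.143), was among those called, at -0.46 (adjusted p = 0.0275). Imprinted genes rose in 2 and fell in 6 of 34, or 3 and 9 adjusted over the list alone (0.0643): the fetal growth factor gene Igf2 fell (-2.14 ± 0.33, 120 ± 29 against 529 ± 190 CPM), H19 fell (-3.46 ± 0.59, 0.571 against 5.91 CPM), and Peg10 (1.51 ± 0.32) and Ddc (1.14) rose. Igf2 and Peg10 also went with the set of replicate numbers, in the direction that the unequal sets would add to these changes. In pMXs replicates 2, 100 and 250 Igf2 was 313, 607 and 668 CPM, H19 2.03, 9.35 and 6.36, and Peg10 736, 479 and 431. In Tet2-WT replicates 1, 2 and 250 Igf2 was 106, 100 and 153 CPM and Peg10 2010, 1710 and 981. Beta-catenin targets rose in 1 and fell in 3 of 16, or 1 and 5 adjusted over the list alone (0.0619). The pluripotency network rose in 5 and fell in 3 of 31, or 6 and 5 adjusted over the list alone (0.853), with Gdf3 at 0.75. Lin28a (1.86 against 4.01 CPM) and Esrrb (0.517 against 1.12 CPM) were among those that fell. Both calls were lost with the replicate block (edgeR adjusted p = 0.0571 and 0.089). P53 targets rose in 4 and fell in 1 of 24, or 6 and 2 adjusted over the list alone (0.182), with Gdf15 at 1.20. Endothelial markers rose in 2 and fell in 4 of 11, or 3 and 5 adjusted over the list alone (0.364), with the VEGF receptor gene Kdr at -1.85.

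Cell cycle genes rose in 1 of 30 (0.182), while the list was called lower with the replicate block (0.0172), and glycolysis genes rose in 2 of 21 (0.264), Eno3 (0.59) and Pfkp (0.40). Neural markers rose in 1 and fell in 4 of 17 (0.323), with Nes at 0.74, Gap43 at -1.89 and Map2 at -0.81. ERK pathway targets rose in 2, Ereg (1.08) and Ccnd1 (0.41), and fell in 2 of 23 (0.781), with Spry1 at -0.78. Skeletal muscle markers rose in 1 of 8, Chrna1 (3.53, 1.07 against 0.099 CPM), and in 2 adjusted over the list alone (0.487). Extraembryonic markers rose in 1 and fell in 2 of 13, or 4 and 2 adjusted over the list alone (0.881). The methylation machinery rose in 1, Tet2 itself, and fell in 1 of 22 (0.558). Germline genes rose in 1 of 11 (0.788), the OKSM factors in 0 of 4 (0.123), and erythroid markers in 1 of 2, Hbb-y (2.31, list 0.122). Median and mean differed in sign for the methylation machinery, pluripotency and germline lists.

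Tet2-E against pMXs asks what the stalling mutant changes. Besides Tet2, 6 genes passed in edgeR, none of them an OKSM gene. Lgals3, the galectin-3 gene, rose by 0.79 ± 0.11 (240 ± 33.9 against 138 ± 16.3 CPM, n = 4 and 3, edgeR adjusted p = 0.0229), and Chst3 rose by 0.53 ± 0.09 (adjusted p = 0.0401). Cxcl12 fell by 0.99 ± 0.14 (46.4 against 92.1 CPM, adjusted p = 0.0229), the phosphodiesterase gene Enpp1 by 0.90 ± 0.14, and the zinc-finger genes Zfp618 by 0.75 ± 0.12 and Zfp467 by 0.74 ± 0.12 (adjusted p = 0.0356 for all 3). Lgals3, Enpp1, Zfp618 and Zfp467 were picked after their values were seen. With Tet2-WT all 6 changed in the same direction, Lgals3 by 1.42, Enpp1 by -1.86, Zfp618 by -0.79 and Zfp467 by -1.06. Pou5f1 (0.09, adjusted p = 0.894), Sox2 (0.03, 0.97), Klf4 (0.01, 0.986) and Myc (0.01, 0.992) did not pass.

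The count of 7 genes, 3 higher and 4 lower, depended on the setting, and 1363 genes had an unadjusted p under 0.05. It was 50 without Tet2-E replicate 100, the library with 581 CPM of Tet2, and 2 without replicate 2. It was 1 without Tet2-E replicate 1, pMXs replicate 100 or pMXs replicate 250. With the replicate block it was 93, 39 higher and 54 lower, with the set of numbers as a term 152, and with DESeq2 138. With the block, the collagen genes Col3a1 (adjusted p = 0.0239, 0.0608 without it) and Col11a1 (0.0205, 0.0857 without it), Aldh3a1 (0.00494, 0.0942), Itgam (0.0287, 0.0645), H19 (0.00494, 0.132), Igf2 (0.00673, 0.328) and Lum (0.0172, 0.556) passed. Of the 92 genes other than Tet2 called with the block, 91 were also called for Tet2-WT in the same direction, and both comparisons share the pMXs libraries, which raises such an overlap by an amount not computed here.

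Of the lists, 3 were called by camera for Tet2-E and 0 by camera with an estimated correlation or by fry, and Tet2 was the single member of any list to pass over all genes tested. Mesenchymal genes were lower, with 0 of 32 passing, or 1 higher and 2 lower adjusted over the list alone (0.0267, and adjusted p = 0.159 with an estimated correlation). Macrophage markers were higher, with 0 of 7 passing, or 1 adjusted over the list alone (0.0267, and adjusted p = 0.534 with an estimated correlation). Keratinocyte markers were higher with 0 of 16 passing either way (0.0344, and adjusted p = 0.772 with an estimated correlation), a call also lost with the replicate block (0.0771). Each was lost without pMXs replicate 100 (0.0547, 0.0546 and 0.0556) and without pMXs replicate 250 (0.059, 0.059 and 0.137). The mesenchymal list was also lost without Tet2-E replicate 100 (0.139) or 250 (0.0652), and the macrophage and keratinocyte lists without Tet2-E replicate 1 (0.0611 and 0.0996). The other 18 lists were not called, and of these the methylation machinery, pluripotency and beta-catenin lists had a median and a mean of opposite sign.

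Tet2-WT against Tet2-E asks directly whether the mutant differs from the wild type. P2rx7 was 1.84 ± 0.10 higher with Tet2-WT (n = 3 and 4, edgeR adjusted p = 1.04e-07), Mst1 1.90, Avil 1.67 and Chst3 1.13 (adjusted p = 2.4e-06). Srgn, a proteoglycan gene of blood cells, was 3.71 ± 0.31 higher (6.51 against 0.532 CPM, adjusted p = 1.04e-05). Cxcl12 was lower with Tet2-WT (-1.42, adjusted p = 8.56e-05), as were Cpxm1 (-1.11) and the matrix gene Mfap4 (-1.56). The OKSM genes did not pass: Klf4 was at 0.17 (adjusted p = 0.38), Pou5f1 at 0.23 (0.493), Myc at 0.18 (0.683) and Sox2 at 0.17 (0.685). All of these values were above 0, so a modest difference is not excluded.

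In all, 675 genes differed between Tet2-WT and Tet2-E, 355 higher and 320 lower with Tet2-WT, and 185 of them by at least 2-fold, 116 higher and 69 lower. Without Tet2-WT replicate 1 the count was 335, and without Tet2-WT replicate 2 it was 339. Within replicate numbers 1 and 2, 1015 genes were called, and within 100 and 250, with 1 Tet2-WT library, 472. The bone morphogenetic protein gene Bmp6 (1.18), Adh7 (1.01) and Mroh6 (1.66) were also among the higher genes with the smallest p. On the lower side were Cdh3 (-1.02), the glutamate transporter Slc1a6 (-1.45), Pamr1 (-1.28), the netrin receptor Unc5c (-1.42) and the adhesion gene Alcam (-1.26).

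**Figure D2:**
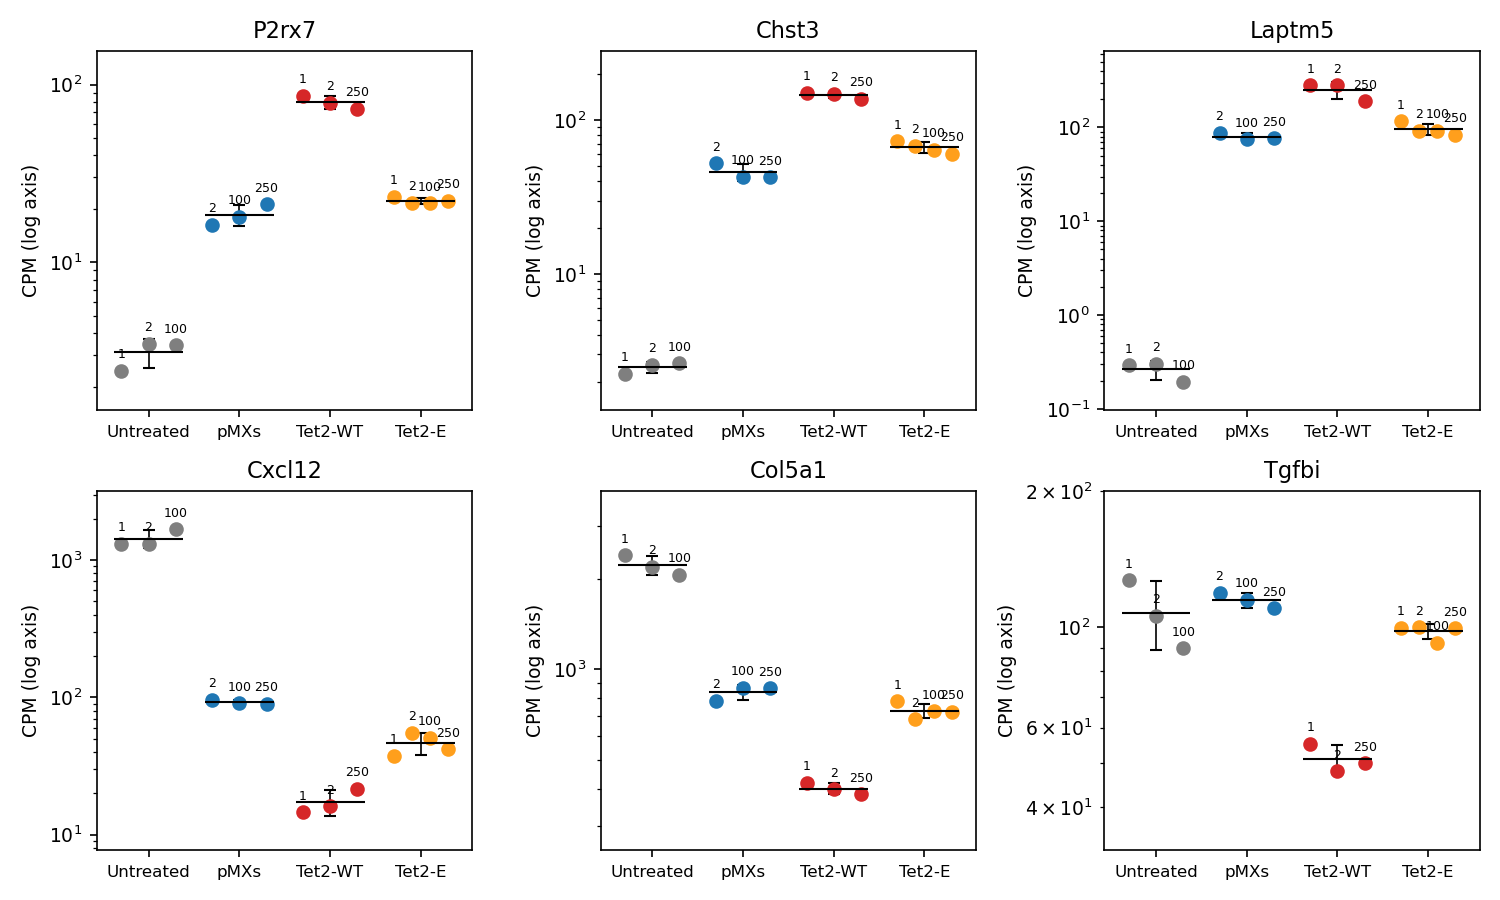
CPM (log axis) of P2rx7, Chst3, Laptm5, Cxcl12, Col5a1 and Tgfbi in each library of the 4 groups, with dots labelled by replicate number, lines for means and bars for the SD. With Tet2-WT the first 3 genes lie above pMXs and the last 3 below, and P2rx7 averages 79.5 CPM against 18.5.

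Camera called 9 lists between Tet2-WT and Tet2-E. Mesenchymal genes were lower with Tet2-WT in 9 and higher in 0 of 32, or 16 and 1 adjusted over the list alone (9.16e-13, and adjusted p = 0.00027 with an estimated correlation), with Col5a1 at -0.86. TGF-beta targets were lower in 7 and higher in 0 of 23, or 11 and 1 adjusted over the list alone (1.41e-07, and adjusted p = 0.102 with an estimated correlation), with Tgfbi at -0.94 ± 0.10. Tgfbi, Col1a1, Acta2 and Tagln belong to both this list and the mesenchymal one. Macrophage markers were higher in 4 of 7, and in 4 adjusted over the list alone (9.24e-06, and adjusted p = 0.102 with an estimated correlation), Laptm5 by 1.39 ± 0.13, Itgam by 1.71 and Cd68 by 1.25. Interferon response genes were higher in 3 of 28, or 10 higher and 1 lower adjusted over the list alone (1.59e-05, and adjusted p = 0.144 with an estimated correlation), with Xaf1 at 0.92. Keratinocyte markers were higher in 2 of 16, or 3 adjusted over the list alone (0.000208, and adjusted p = 0.268 with an estimated correlation), with Col17a1 at 2.33.

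Epithelial genes were higher in 2 of 28, Krt18 (1.33) and Krt8 (1.04), or 3 adjusted over the list alone (0.000473, and adjusted p = 0.483 with an estimated correlation), and the call was lost without Tet2-WT replicate 2 (0.0733). Cell cycle genes were lower as a list with 0 of 30 passing (0.00401, and adjusted p = 0.663 with an estimated correlation). Glycolysis genes were higher in 1 of 21, Eno3 (0.57), or 2 adjusted over the list alone (0.0125, and adjusted p = 0.551 with an estimated correlation), and the call was lost without Tet2-WT replicate 2 (0.0505) or Tet2-E replicate 2 (0.298). Beta-catenin targets were higher in 1 and lower in 1 of 16, or 1 and 4 adjusted over the list alone (0.0342, and adjusted p = 0.174 with an estimated correlation), and the call was lost without Tet2-WT replicate 250 (0.0639) or Tet2-E replicate 100 (0.0712). The other 12 lists were not called, and of these the pluripotency, germline, ERK and extraembryonic lists had a median and a mean of opposite sign. Neural markers (0.101) were called lower with the replicate block (0.0352). Members of these 12 lists that passed included Gdf3 (0.88), Nap1l5 (-1.15), Eng (0.49) and Lin28a, which was lower with Tet2-WT (1.86 against 4.16 CPM).

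**Figure D3:**
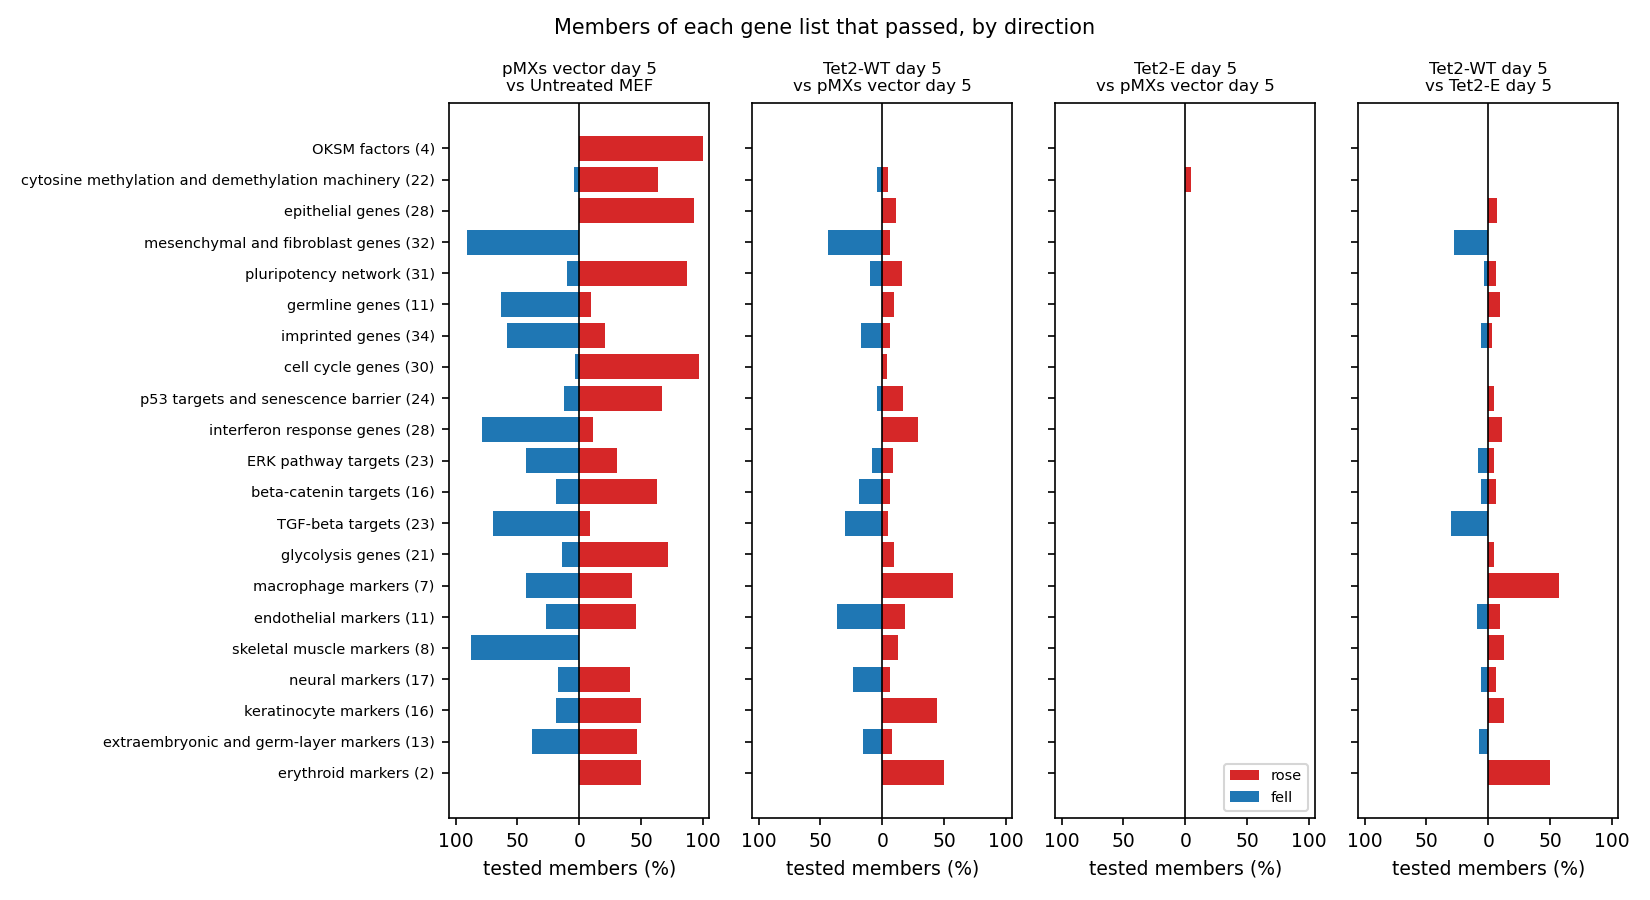
Share of the tested members of each gene list (%, number tested in parentheses) that rose (right, red) or fell (left, blue) over all genes tested, in the 4 comparisons. Of the mesenchymal genes 14 of 32 fell with Tet2-WT against pMXs, and in Tet2-E against pMXs Tet2 is the single member of any list that passed.

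The genes that changed with Tet2-WT were then followed in Tet2-E. Of 1829 such genes other than Tet2, 1737 (95%) had the same sign with Tet2-E. In simulated counts with the same shared control libraries and Tet2-E equal to pMXs the value was 64.7% (63.1 to 65.8 over 20 simulations), with 2650 genes called for Tet2-WT on average. With both vectors equal to pMXs, the genes ranked first for Tet2-WT, in the same number, gave 88.4% (86.9 to 89.7). The simulations leave out the sets of replicate numbers, which are unequal between groups, and within numbers 1 and 2, with 1 pMXs library, the share was 86.8%, within 100 and 250 it was 93.7%. Signed by the Tet2-WT direction, the median log2 fold change was 0.24 for Tet2-E, against 0.05 in the first simulations and 0.14 in the second. Per library the median shift from the pMXs mean was 0.64 ± 0.06 with Tet2-WT (SD, n = 3), 0.24 ± 0.08 with Tet2-E (n = 4) and 0.00 ± 0.06 with pMXs (n = 3). The pMXs libraries form that mean, so their 0.00 is set by construction. The Tet2-E value went with the sets, at 0.321 and 0.302 in replicates 1 and 2 and 0.164 and 0.177 in 100 and 250. In pMXs replicates 2, 100 and 250 it was 0.062, 0 and -0.065. Choosing the genes by their change with Tet2-WT raises the Tet2-WT value. Tested directly, 618 of the 1829 genes (33.8%) differed between Tet2-WT and Tet2-E in the Tet2-WT direction and 0 in the other, though both edgeR tests use the same Tet2-WT libraries. The count was 320 of 1106 genes without Tet2-WT replicate 1 and 322 of 1134 without Tet2-WT replicate 2. With a term for the set of replicate numbers it was 904 of 2059. No value without a real difference was computed for this count. Among the 6 genes that changed with Tet2-E, Cxcl12, Chst3, Lgals3 and Enpp1 moved further with Tet2-WT (adjusted p = 8.56e-05, 2.4e-06, 0.00338 and 0.00416 between Tet2-WT and Tet2-E). For Zfp467 (-0.32, adjusted p = 0.208) and Zfp618 (-0.04, adjusted p = 0.949) a difference did not pass.

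**Figure D4:**
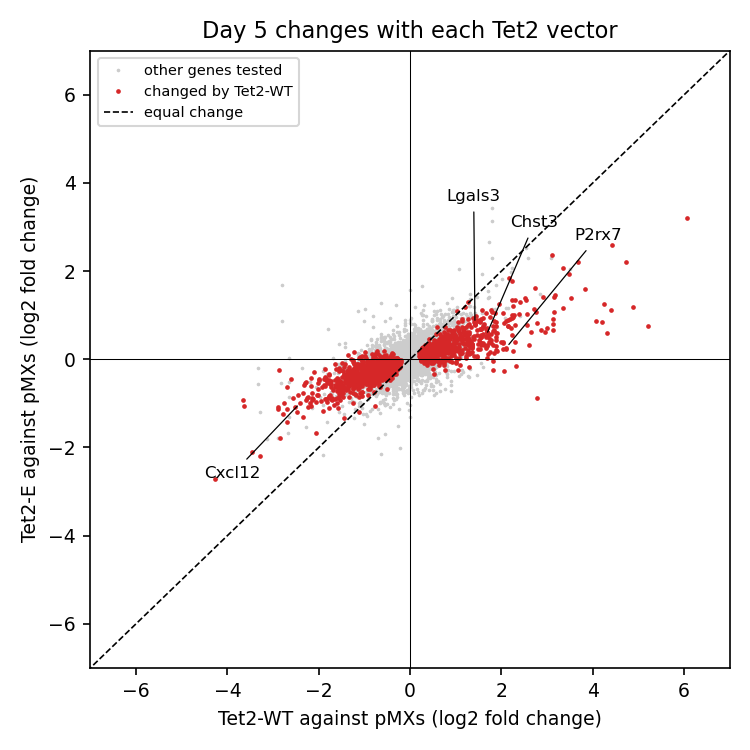
Log2 fold change of each gene with Tet2-E against pMXs (vertical) and with Tet2-WT against pMXs (horizontal), with the genes called for Tet2-WT in red and a dashed line at equal change. Of the 1829 called genes other than Tet2, 1737 have the same sign on both axes, and both axes share the pMXs libraries.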

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

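The tests of macrophage transcripts, of held-out Tet2-WT libraries, of the share of MEFs, of how far the day 5 change had gone and of the lists with a term for the set of replicate numbers were chosen only after the results they bear on had been seen. A single library was tested against the others of its group, by Dixon's ratio of its gap to the range, in the 4 Tet2-E libraries, and the groups of 3 were not tested. Of 141 named genes tested, 6 had a library set apart, where chance gives 7.05, since chance flags about 1 in 20. Tet2 was 581 CPM in Tet2-E replicate 100 against 1300 to 1400 in the others, and the same library was apart for the receptor gene Flt1 (4.74 against 3.53 to 3.67 CPM) and for Tgfbi (92.4 against 99.5 to 100 CPM). Replicate 1 was apart for Slc2a3 (309 against 220 to 229 CPM) and Isg15 (1.57 against 0.747 to 0.884 CPM), and replicate 2 for the tight-junction gene Ocln (3.32 against 2.43 to 2.57 CPM). A pattern over libraries is not shown by a number of departures this close to chance, and no biological explanation for them was tested.

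Genes changed by Tet2-WT moved less with Tet2-E. To keep the choice of genes apart from the value, each Tet2-WT library was held out in turn and measured on genes called without it. The held-out libraries then lay above the 3 Tet2-E libraries with at least 1300 CPM of Tet2 by a mean of 0.393 on the log2 scale (SD of held-out libraries 0.144). The differences were 0.496, 0.444 and 0.24 for Tet2-WT replicates 1, 2 and 250. The smallest difference from Tet2-E libraries of the same set of replicate numbers was 0.352. These values argue against less Tet2 RNA and against unequal sets as the whole cause, and a weaker action of the stalling mutant on the same genes is a hypothesis that stays open. Protein levels, the share of infected cells and catalytic activity were not measured in these data and may also differ.

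The macrophage-associated genes Laptm5, Itgam, Cd68 and Csf1r rose with Tet2-WT. Macrophages in the culture would bring their abundant transcripts (Lyz2, Tyrobp, Fcer1g, Ctss, C1qa, C1qb, C1qc and Cd52), but the sum of these changed by -0.0136 CPM, from 0.18 CPM with pMXs to 0.166 CPM, while Laptm5 rose by 171 CPM, and in untreated MEFs the sum was 2.59 CPM. With a term for the set of replicate numbers the median log2 fold change of the 7 tested list members was 1.598, against 1.722 without it, and camera still called the list (adjusted p = 5.27e-05), which argues against the unequal sets as the whole cause. A change of these genes in the reprogramming cells themselves is thus a hypothesis that stays open, as is a change in feeder cells. No protocol step sorted the cultures, and 12 of the 19 listed markers in the table were too low to test.

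The mesenchymal list fell with Tet2-WT. Fewer MEFs with the expression of the untreated ones are argued against as the whole cause. The 20 genes abundant in untreated MEFs that had fallen at least 32-fold by day 5 kept a median of 2.16% of that level with pMXs. They were chosen by this fall, so the small share follows from the choice. It limits only MEFs that still express these genes as untreated ones do. Complete loss of such a share would give a median of 23.2% (3.67 to 47.5%) of the fall of the 14 members that fell. These 20 genes were themselves lower with Tet2-WT (median -0.973), so fewer such cells may carry part of it. With a term for the set of replicate numbers the list median was -0.51, against -0.50 without it, and camera called the list (adjusted p = 1.11e-11), which argues against the unequal sets as the whole cause. Whether the culture was further along the day 5 change was not decided. The 1950 genes that had risen at least 2-fold had a median of only 0.056 (SD between libraries 0.04), while the 2250 that had fallen had -0.26. Of the risen genes 276 were called higher and 79 lower with Tet2-WT, and of the fallen 95 higher and 502 lower. On the first principal component Tet2-WT libraries lay at -52.5 to -46.6, pMXs at -34 to -24 and untreated at 124.4 to 128.7. These counts and positions go with a culture further along, which stays open. Feeder cells, MEFs altered by the medium and an effect of Tet2 on these genes within each cell stay open, since no library here holds feeder cells or such MEFs alone.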

How the results depend on the processing

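The term for the set of replicate numbers and the contrasts within sets were chosen only after the data were seen, and the other settings before. The log2 fold change of Tet2 kept its direction and its call with Tet2-WT in every setting run, and with Tet2-E in every one except the fit of only the 2 groups compared (4.65, adjusted p = 0.0744, over the other settings 1.21e-70 to 0.0021). Counts of changed genes for pMXs against untreated stayed within 1.5 times the reported one throughout. For Tet2-WT against pMXs they ran from 1097 to 1821 when a library was left out (1097 without pMXs replicate 250, 1175 without pMXs replicate 100, 1107 without Tet2-WT replicate 1, 1135 without Tet2-WT replicate 2), were 1260 and 1358 within the sets of numbers and ran from 1697 to 2270 otherwise. For Tet2-WT against Tet2-E they ran from 335 to 675 (335 without Tet2-WT replicate 1, 339 without Tet2-WT replicate 2), with 1052 for the number set, 1015 and 472 within the sets and 639 to 965 otherwise. For Tet2-E against pMXs the reported 7 became 17 with no filter, 93 with the replicate block, 152 with the number set, 26 with a surrogate variable, 138 with DESeq2 and 0 in edgeR on only the 2 groups compared (1342 at an unadjusted p under 0.05), and ran from 1 to 50 when a library was left out: 1 without pMXs replicate 100, pMXs replicate 250 or Tet2-E replicate 1, 2 without Tet2-E replicate 2, and 50 without Tet2-E replicate 100. The pairing check linked day 5 libraries mostly through the sets of numbers, and little was seen of a link by the number itself. The best match of a day 5 library in another day 5 group had its own number for 5 of 10. The block also takes in the sets and so removes spread that they share, while for the other settings the cause was not tested. Of the lists, an estimated correlation left 1 called for pMXs against untreated, 1 for Tet2-WT against pMXs, 0 for Tet2-E against pMXs and 1 for Tet2-WT against Tet2-E. Fry called 8 for Tet2-WT against pMXs and 0 for Tet2-E against pMXs, where a surrogate variable also left 0. Leaving out a library gave 0 to 4 there, with 0 without pMXs replicate 100 or 250 and 1 without Tet2-E replicate 1. The median shift with Tet2-E of the genes changed by Tet2-WT was 0.20 to 0.31 with RLE, the block, the number set, a day 5 library left out or contrasts within the sets. Among named genes, 43 of the 65 passing for Tet2-WT against pMXs and 27 of the 46 for Tet2-WT against Tet2-E kept their call and direction in each setting apart from the contrasts within sets, and 81 of 83 for pMXs against untreated. No called list or named gene changed direction in the settings apart from the contrasts within sets. In those contrasts 10228 (numbers 1 and 2) and 10210 (100 and 250) of the 10234 genes called for pMXs against untreated kept their direction. All genes called in the other comparisons kept theirs. Genes below the filter on low counts, 12 of the 19 macrophage markers in the table among them, were not tested.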

Other observations

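The term for the set of replicate numbers and the choice of Xist and of the genes named for that set came only after the data were seen. Other splits of the same libraries into groups of the same sizes were counted for each comparison. For pMXs against untreated, 1 of 10 splits, the real one, called as many genes, with 0 in edgeR for the highest other split, and the same held for Tet2-WT against pMXs (1 of 10, highest other 0). With 10 splits a share under 0.05 cannot be had. For Tet2-E against pMXs 3 of 35 splits called at least the 7 genes of the real one, so chance is not excluded for that count. The highest other split called 26 genes and set replicates 100 and 250 of both groups against the rest, which points to a structure of the libraries by replicate number. Within the sets 103 genes were called for numbers 1 and 2, with 1 pMXs library, and 83 for 100 and 250. For Tet2-WT against Tet2-E 1 of 35 splits called as many genes as the real one (675), and the highest other, also along the sets, called 167, a share of 0.0286. The day 5 libraries are linked, however, mostly through the sets of numbers. If same numbers also mark pairs, the 7 other splits that part 3 same-number pairs, as the real one does, are too few for a share under 0.05. In edgeR these 7 called 0 genes each in this comparison and in Tet2-E against pMXs. Every split was refitted, and one that mixes the real groups holds their difference within its own groups. This raises the spread and lowers the count, so the counts of 0 do not estimate what chance alone would call.

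The set of replicate numbers itself went with 1165 genes, 548 higher and 617 lower in replicates 100 and 250, and with 2133 when the day 5 libraries alone were fitted. Pstpip1 (-1.04), Col7a1 (-1.06), the histone gene Hist1h3b (-1.02), Uchl1 (-0.88) and the imprinted gene Peg10 (-0.72) were lower in 100 and 250, and Mgp (0.78), Lum (1.29), Agtr2 (1.47) and Igf2 (0.73) were higher. Peg10, Lum and Igf2 also changed with Tet2-WT against pMXs, in the direction that the unequal sets of those groups favour. The labels do not say what the numbers stand for.

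Xist was 9.27 CPM in Tet2-E replicate 2, 0.336 to 1.38 CPM in the other day 5 libraries and 5.04 to 7.49 CPM in untreated MEFs.

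Genes that rose from untreated cells to pMXs and rose again with Tet2-WT numbered 465, where independence gives 308, and genes that fell in both numbered 701, where it gives 333. Those that rose and then fell numbered 128 against 334, and those that fell and then rose 220 against 308. The pMXs libraries enter both comparisons with opposite sign, which by itself would favour opposite directions. Tgfbi was 108 ± 18.5 CPM in untreated cells and 115 ± 4.53 CPM with pMXs (n = 3 each), and fell with Tet2-WT to 51.1 ± 3.73 CPM.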
